A study of Mus musculus with 2 samples.

How the data were processed

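The data are DNase-seq of the adrenal gland of male B6CASTF1/J mice at 14 days, 2 samples in 1 group, each from 3 males per the labels. Per the labels' protocols nuclei were isolated from the tissue. Sequencing instruments were named for replicate 2 only. Per the deposited descriptions, each sample has its own files on mm10, derived from its own filtered alignments, so replicates were not pooled. The aligner, the peak caller and their versions are not given in the sources used here. 4 kinds of file were used per sample. The first is a list of short intervals where the deposited value is the FDR of the DNase cut rate, a q-value, all below 0.05. The next 2 are peak lists of different length in which the authors' value for each peak is a signal, a density that is a whole multiple of one step in 100% of values below 1 (tolerance 0.1 step). The depth of a sample is not stated otherwise, and a ratio of 1.73 between the samples' tags follows only if one step is one tag on a CPM scale. The fourth is a list of footprint calls in which the authors gave the same FDR, a q-value of 0.01, for every call.

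The shorter peak list was used as the main one. Nearly every peak in it (above 99.99% in both samples) contained an interval with an FDR of at most 0.001. The longer list, with 210257 and 136015 peaks, was an alternative. The signal served to rank and describe peaks. Values of both replicates are given side by side, and a ratio between them appears in the closing section only.

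Genes were those annotated as protein-coding in GENCODE vM21 (21853 genes, 54361 TSS positions) on the GRCm38 sequence, which has the coordinates of mm10. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks were shared when they overlapped by at least 1 base. Location was assigned in the order promoter (within 1 kb of a TSS), exon, intron, intergenic. A gene's promoter signal is the highest among the peaks within that window, also where such a peak lies near a TSS of another gene. Distal regions were assigned to the nearest TSS within 100 kb, and a gene's territory is the stretch nearer to it than to its neighbours. Promoters of each list were compared with all other genes by a two-sided Fisher's exact test, and distal counts with 10000 random lists from 10 territory classes by a two-sided permutation test, each with Benjamini-Hochberg adjustment over 22 lists. Promoter CpG content was the ratio of observed to expected CpG within 500 bp of the TSS, the highest over a gene's TSSs. Motifs were matched exactly as consensus sequences on both strands in 200 bp windows. Shares and ratios have exact 95% binomial intervals, and means have SDs over n = 2. The 2 samples allow no p-value between samples.

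The lists, the motifs, the tests, 32 alternatives and the rule for named genes were fixed before the data were examined. The rule takes 30 genes fixed by name. From each list it adds the 2 with the highest mean promoter signal among those open in both samples and the 2 first in the alphabet among those open in neither. It also takes the 10 genes with the most shared distal regions, and the 6 highest and 3 lowest motif ratios. Promoter motifs, footprint motifs, distal regions at named genes and further list members printed in the text were chosen after their values were seen. The lists cover steroidogenesis, cortical zonation, cholesterol synthesis, chromaffin cells, capsule, endothelium, immune cells, Schwann cells, erythroid cells, kidney, adipocytes, liver, muscle, cortical neurons, epidermis, germ cells, gonadal somatic cells, pancreas, eye, housekeeping, immediate early and glucocorticoid response genes. No gene is in more than 1 list, and the list called cortical neuron also holds the glial genes Olig1 and Gfap. Of 334 entries 333 matched the annotation. Which of these genes the gland transcribes was not measured. Some genes that the rule takes are not reported here. Alternatives added after seeing the data were the same number of top peaks for promoter lists, CpG-matched promoter lists in one replicate at a time, and random lists matched on territory and promoter signal for distal regions.

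The tests of lists, motifs, footprints and replicate ratios were tested on simulated data, and the sharing and location of peaks were not. Fisher's test called 97.5% of lists planted with 97% open genes and 0.833% of unchanged ones. Where opening depended on CpG content, the CpG-matched test called 100% of planted lists and 0% of unchanged lists low in CpG content, of which Fisher's test called 18.3%. The distal test called 46.4% of lists planted at 2.5 times the rate and 3.33% of unchanged ones, so a list that misses its threshold may still differ. In the motif step 5% of windows were moved onto NR5A1 sites and 4.96% were recovered, which checks the counting only. At random windows 2 of the 26 motifs had an interval that excluded 1. Footprints placed at random in peaks of replicate 2 had a median motif ratio of 1.02. This does not check for an effect of where the real footprints lie within their peaks. For the ratios between replicates, 84% of lists of 20 lowered by 0.5 on the log2 scale were found, and 3.5% of unchanged lists lay outside the 2.5 to 97.5 percentiles.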

Results

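DNase-seq maps accessible chromatin as sites that the nuclease DNase I cuts in isolated nuclei. It was applied here to the adrenal gland of male B6CASTF1/J mice, an F1 cross, at 14 days of age. The labels gave 1 group of 2 biological replicates, each a sample from 3 males and each a separate biosample. Both carry the same donor identifier, so the spread between them is that between these 2 samples. With a single group there was no comparison between conditions. The design allowed a comparison of the replicates with each other, and comparisons of gene lists, regions and motifs within the tissue, in which genes or regions are the units and are not independent replicates. All coordinates are on mm10. Replicate 1 had 128446 peaks covering 25.6 Mb and replicate 2 had 83475 peaks covering 15.3 Mb. The median peak was 180 bp wide in both. Peak signal, the authors' own value for each peak, is a whole multiple of one step per sample. If one step is one tag on a CPM scale, replicate 1 held 1.73 times as many tags as replicate 2, and the median peak 241 tags in replicate 1 and 146 in replicate 2. Intervals around shares cover counting error only.

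Of the peaks of replicate 1, 56.5% (95% exact binomial interval 56.3 to 56.8%) were overlapped by a peak of replicate 2. Of the peaks of replicate 2, 87.1% (86.8 to 87.3%) were overlapped by a peak of replicate 1. Merged over both samples there were 136755 regions, of which 71349 were found in both, 54658 in replicate 1 only and 10748 in replicate 2 only. Strong peaks were almost all shared. In the strongest decile by signal the overlapped share was 99.4% in replicate 1 and 99.8% in replicate 2, and in the weakest decile it was 11.5% and 61.4%. With the same number of top peaks taken from each sample, the shares were 74.1% and 74.3%.

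**Figure D1:**
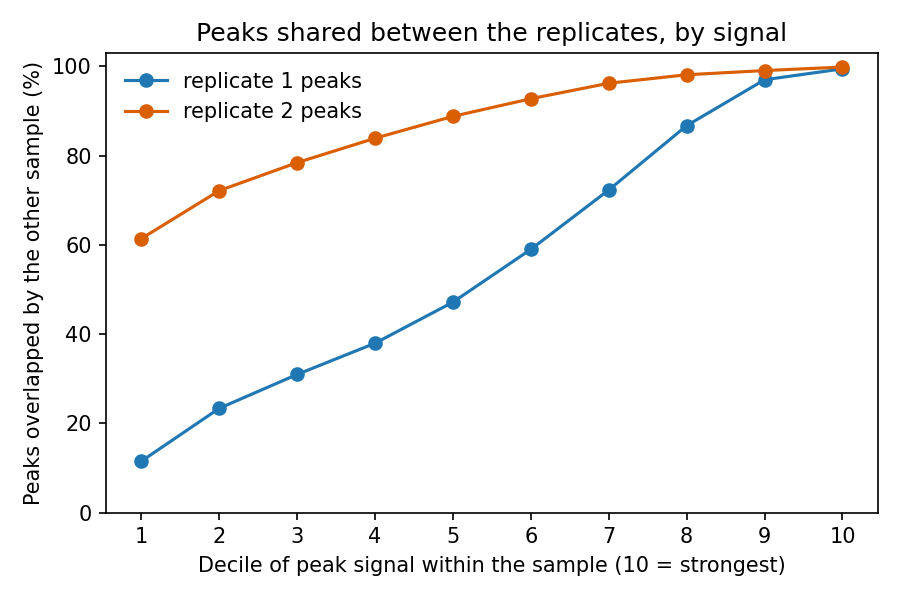
Share of each sample's peaks overlapped by a peak of the other sample (percent, vertical axis) by decile of peak signal within the sample (horizontal axis), one line per replicate. Both lines climb from the weakest decile (11.5% and 61.4%) to the strongest (99.4% and 99.8%).

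Promoter peaks were those within 1 kb of a protein-coding transcription start site (TSS). Their share was 26.3% ± 2.36 (SD, n = 2), with 33.6% ± 1.21 in introns, 4.09% ± 0.921 in exons and 36.0% ± 0.226 between genes. Promoter peaks had the highest signal in both samples, with a median of 2.27 in replicate 1 and 1.93 in replicate 2. Intergenic peaks had a median of 0.786 and 0.869.

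With a peak near any TSS counted, promoters of steroid hormone synthesis genes were accessible more often than those of genes with matched CpG content. Those of germ cell genes were accessible less often. A promoter was called open when it held a peak in both samples. Of 21853 protein-coding genes, 13690 (62.6%) were open, 1481 had a peak in replicate 1 only, 92 in replicate 2 only and 6590 in neither. Among the 22 gene lists, 19 of 22 steroidogenic genes were open (86.4%), compared with 55.1% in random lists with the same promoter CpG content (two-sided permutation test, adjusted p = 0.00147). The adipocyte list had 12 of 13 genes open (92.3%, compared with 40.2% in matched lists, permutation adjusted p = 0.00147). Kidney (2 of 16, 12.5% compared with 43.9%, permutation adjusted p = 0.0106), germ cell (1 of 11, 9.09% compared with 59.3%, permutation adjusted p = 0.00147) and cortical neuron genes (6 of 15, 40% compared with 74.4%, permutation adjusted p = 0.00220) were open less often. These 5 lists were the ones past 0.05 when CpG content was matched. Random lists were not matched on the number of TSSs per gene, and CpG matching was not run with only the 5′-most TSS. The raw p for the steroidogenesis, adipocyte and germ cell lists, 0.0002, is the smallest that 10000 random lists can give. The test fixed as the main one, Fisher's exact test against all other genes, called 14 of 22 lists, and 3 of those 14 were among the 5. In Fisher's exact test steroidogenesis had an adjusted p of 0.0399, which became 0.0541 in replicate 1 alone, 0.0821 with peaks above each sample's median signal, 0.112 with the same number of top peaks from each sample, an alternative chosen after seeing the data, and 0.359 with only the 5′-most TSS of each gene. The low counts of kidney and cortical neuron genes came from replicate 2. In replicate 1, 8 of 16 kidney promoters held a peak (Fisher's exact test, adjusted p = 0.136) and 13 of 15 cortical neuron promoters, 17.3 percentage points above other genes (Fisher's exact test, adjusted p = 0.200). The cortical neuron and adipocyte lists did not pass Fisher's exact test in both samples together (adjusted p = 0.137 and 0.0586). CpG matching in one replicate at a time was chosen after seeing the data. It kept steroidogenesis, adipocyte and germ cell past 0.05 in both, and kidney (permutation adjusted p = 0.0123) and cortical neuron (0.00660) in replicate 2 only, with a permutation adjusted p of 1 for each of them in replicate 1.

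**Figure D2:**
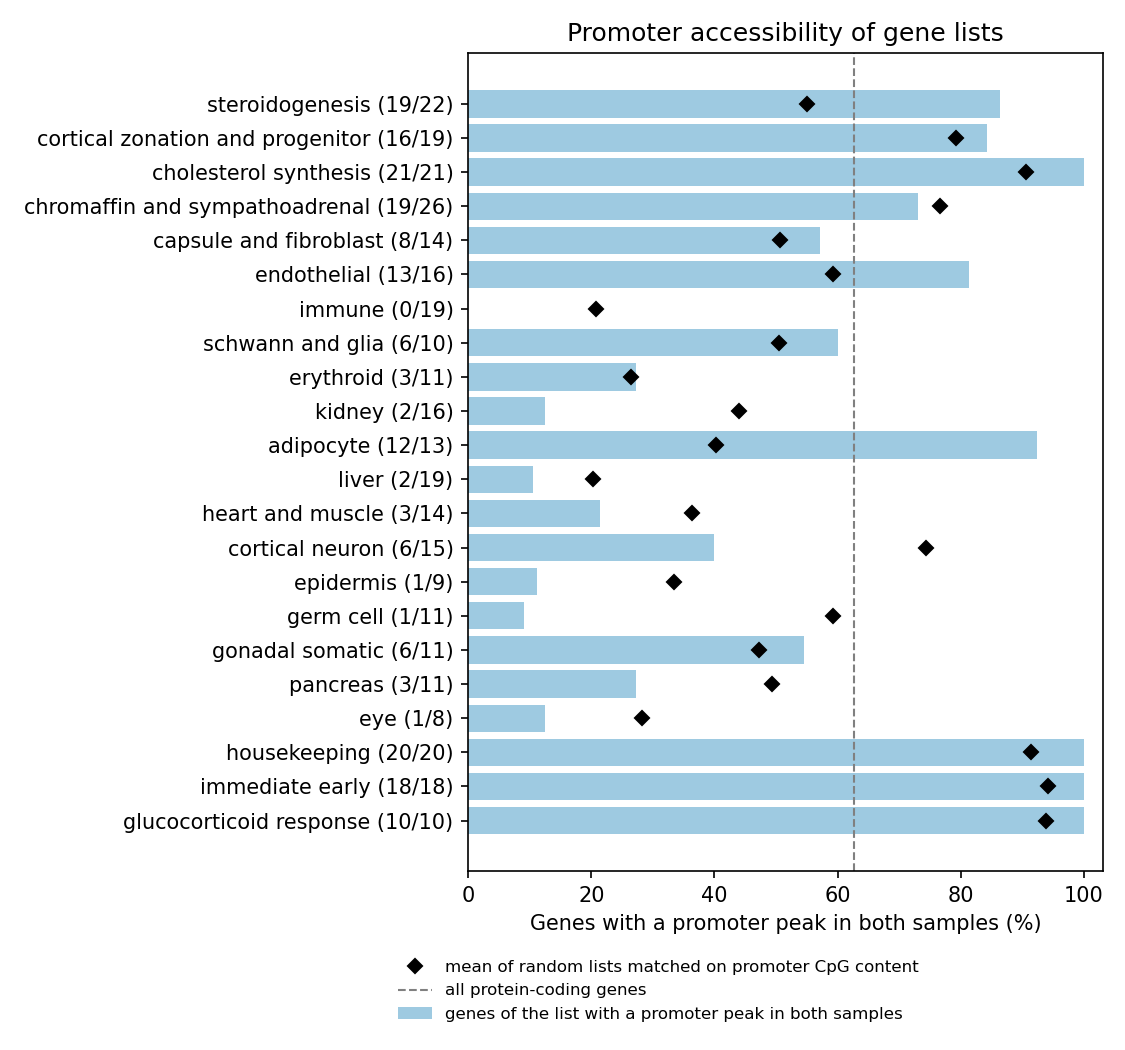
Share of each list's genes with a promoter peak in both samples (bars, percent, with counts beside the names), the mean of random lists matched on promoter CpG content (diamonds) and the share over all protein-coding genes (dashed line, 62.6%). The adipocyte bar (92.3%) stands farthest above its diamond (40.2%), and the germ cell bar (9.09%) farthest below (59.3%).

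Among the steroidogenic genes, the strongest promoter peaks by mean signal were at Npc1, which exports cholesterol from lysosomes (signal 16.1 in replicate 1 and 11.6 in replicate 2), and Por, the electron donor of microsomal P450 enzymes (14.5 and 12). Star, which carries cholesterol into mitochondria, had a peak at chromosome 8, 25806201 to 25806580, at its TSS (4.47 and 3.68) and a further one at 25808301 to 25808620. Cyp11a1, which makes pregnenolone from cholesterol, had its shared promoter peak at chromosome 9, 58014861 to 58015120 (4.44 and 2.89). It lay 320 bp from an annotated TSS inside the gene, which starts at 58006411 on the plus strand. Within 1 kb of that start only replicate 1 had peaks, with signals of 0.199 to 0.303. The promoter peaks of Scarb1, a receptor for lipoprotein cholesterol, Mrap, the accessory protein of the ACTH receptor, and Nr5a1, the transcription factor SF-1, had signals of 10.97 and 4.70, 5.50 and 4.71, and 6.41 and 2.58. Cyp21a1, the 21-hydroxylase, had 1.54 and 2.15, Cyp11b1, the 11β-hydroxylase, had 1.33 and 1.24, and Nr0b1 had 0.714 and 0.483. Cyp11b2, aldosterone synthase, had a promoter peak in replicate 1 only (0.367), and Mc2r, the ACTH receptor, in replicate 2 only (0.766). Hsd3b1 had none in either sample, and Hsd3b6 had 0.483 and 0.552. Hsd3b1, Hsd3b6, Cyp11b1, Cyp11b2 and Cyp21a1 have close relatives in the genome, and whether reads could be placed uniquely at them was not tested.

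All 21 cholesterol synthesis promoters were open, led by Dhcr7 (16.7 and 12.2) and Insig1 (16.4 and 10.4). All 20 housekeeping (Rplp0 17.4 and 11.5, Psmb2 18.9 and 8.21, Actb 16.3 and 10.04, Gapdh 11.3 and 6.93), 18 immediate early (Jund 17.9 and 10.6, Jun 14.1 and 13.5) and 10 glucocorticoid response promoters (Fkbp5 16.7 and 9.95, Per1 14.5 and 10.4) were open too. These 4 lists passed Fisher's exact test (adjusted p from 0.000485 to 0.0338) but not the comparison with CpG-matched lists, in which 90.6 to 94.1% of genes were open. Cortical zonation and progenitor genes were open in 16 of 19 cases (Ctnnb1 14.2 and 7.61, Znrf3 10.7 and 6.73), and all 19 held a peak in replicate 1. Fisher's exact test gave an adjusted p of 0.0804, 0.00474 in replicate 1 alone, 0.0199 with the longer peak list and 0.0415 within 2 kb. With CpG matching the permutation adjusted p was 0.856, and 0.124 in replicate 1 alone. Akr1c18, which inactivates progesterone, had 0.514 and 0.476.

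Of 26 chromaffin and sympathoadrenal genes, markers of the adrenal medulla, 19 were open in both samples, which did not pass Fisher's exact test (adjusted p = 0.365). In replicate 1, 24 of the 26 had a promoter peak, and in that sample alone the list passed Fisher's exact test (adjusted p = 0.0188) but not the comparison with CpG-matched lists (84.6% open, permutation adjusted p = 0.549). Slc18a1, a vesicular monoamine transporter, had the highest promoter signal of the list (17.2 and 8.43). Whether that peak belongs to the promoter of a neighbouring gene was not tested. Chgb came next (10.99 and 4.15), and Chga had 5.37 and 1.46. Th, the rate-limiting enzyme of catecholamine synthesis, had 1.23 and 0.738, Dbh 0.981 and 1.00, and Hand2 1.39 and 0.794. Pnmt, which makes adrenaline, and Ddc had no promoter peak.

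The other lists of cell types of the gland were open in 13 of 16 endothelial genes (Esam 3.55 and 3.05, Flt1 4.47 and 1.70, none at Plvap and Tek), 8 of 14 capsule and fibroblast genes (Pdgfra 7.57 and 2.76, Gli1 5.09 and 2.88, none at Lum and Tcf21), 6 of 10 Schwann cell and glial genes (Erbb3 4.33 and 1.30, none at Cdh19), 3 of 11 erythroid genes (Epor 2.62 and 1.39, none at Alas2 and Gata1) and 0 of 19 immune genes (none at Adgre1 and Aif1). Erythroid promoters were below other genes in Fisher's exact test (adjusted p = 0.0399, lost within 2 kb, 0.0810, and with only the 5′-most TSS, 0.0879) and close to CpG-matched lists (26.4% open). Immune promoters were below other genes in Fisher's exact test (adjusted p = 1.63e-07) but not past the threshold against CpG-matched lists (20.7% open, permutation adjusted p = 0.0535). The count of 0 came from replicate 2, where the list passed with CpG matching (permutation adjusted p = 0.0455). In replicate 1 5 of 19 were open (26.3% compared with 30.05% in CpG-matched lists, permutation adjusted p = 1). Against all other genes the immune list kept its call in Fisher's exact test in replicate 1 alone. Low counts were also found for genes of liver (2 of 19, Apoa2 2.05 and 1.98, Apob 2.68 and 0.745, none at Alb and Ahsg), heart and muscle (3 of 14, Ryr2 3.92 and 1.75, Ckm 2.80 and 1.71, none at Myh6, Acta1 and Actc1), epidermis (1 of 9, Krt10 7.74 and 4.32, none at Krt14, Dsg3 and Flg), pancreas (3 of 11, Nkx6-1 3.95 and 1.96, Cela1 3.34 and 1.52, Ins2 2.74 and 1.46, none at Cpa1 and Ctrb1) and eye (1 of 8, none at Crx and Cryaa). Those 5 lists passed Fisher's exact test (adjusted p from 4.19e-05 to 0.0399) but not the CpG-matched one. The Ins2 value came from a peak centred 692 bp from an annotated TSS of the gene. A peak centred 5 bp from another of its TSSs had 0.877 and 0.635. Gonadal somatic genes were open in 6 of 11 cases (Sox9 5.09 and 3.44, Amh 6.35 and 1.77, none at Cyp19a1 and Fshr). Cyp17a1, the 17α-hydroxylase, is in this list and had 1.196 and 1.32.

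In the lists that differed from CpG-matched genes, the open adipocyte promoters had a median signal of 2.19 and 1.55, compared with 7.90 and 4.002 over all open promoters, and the strongest were Plin4 (4.35 and 2.46) and Cidea (4.23 and 2.00). The open steroidogenic promoters also had a lower median signal than all open promoters (6.45 and 3.77). The 2 open kidney promoters were Aqp2 (0.861 and 0.704) and Lrp2 (0.718 and 0.428), and Cubn and Miox had none. Dazl was the open germ cell promoter (9.72 and 5.21), with none at Acr and Ddx4. In the cortical neuron list, which also holds the glial genes Olig1 and Gfap, Olig1 had 4.15 and 1.99, and Neurod6 and Gfap had none.

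Distal accessible regions crowded around genes of the glucocorticoid response, immediate early genes and steroidogenic genes. Of 50624 shared regions more than 1 kb from any TSS, 41363 (81.7%) had their nearest protein-coding TSS within 100 kb. Glucocorticoid response genes had 8.10 such regions per gene, 3.10 times the 2.62 of random lists matched on the size of the gene's territory (two-sided permutation test, adjusted p = 0.00220). Immediate early genes had 6.89 per gene, 2.99 times the 2.30 of random lists (permutation adjusted p = 0.00220), and steroidogenic genes had 3.82, 2.22 times the 1.72 of random lists (permutation adjusted p = 0.00587). The first 2 had a raw p of 0.0002, the smallest that 10000 random lists can give. The other 19 lists lay between 0.456 and 2.08 times their random lists, with adjusted p of 0.379 or more. Chromaffin genes had 2.65 per gene, compared with 3.03 in random lists (permutation adjusted p = 0.833). The steroidogenic fold was 3.96 in replicate 1 alone and 3.47 among peaks above each sample's median signal, where those of immediate early and glucocorticoid response genes were 4.61 and 5.34. It lost its call when random lists were not matched on territory (permutation adjusted p = 0.0506).

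Of the steroidogenic genes fixed by name, Scarb1 had 17 shared distal regions, Mc2r 10, Cyp11a1 8, Nr5a1 6, Mrap and Cyp21a1 5 each, and Star 3. Those of Cyp11a1 lay in introns of it or of a neighbouring gene, except for one between genes at chromosome 9, 58003281 to 58003680 (signal 1.49 and 2.46), 2930 bp from the nearest TSS, which held an NR5A1 motif. At Mrap, the intronic region at chromosome 16, 90740081 to 90740300 (1.66 and 1.30) held one too. Mc2r, with little signal at its promoter, had its strongest distal region at chromosome 18, 68493921 to 68494100 (3.33 and 2.71), between genes and 64691 bp from its TSS. At Scarb1 the strongest by the mean of both samples lay downstream of the gene at chromosome 5, 125252701 to 125253000 (4.95 and 4.13), while in replicate 1 those at 125267141 (5.29 and 2.69) and 125268181 (5.25 and 1.79) were stronger, and the promoter peak was at 125340961 to 125341220. Th had 4 distal regions in introns, the strongest by mean signal at chromosome 7, 142919321 to 142919520 (4.18 and 1.56), and Chga had 5. Over the whole genome, the genes with the most shared distal regions included Pde4d with 34, Gse1 with 33, Auts2 with 32, Zfp423 with 29, Ank3 with 28, and Agap1, Hdac4, Irf2bpl and Kcnma1 with 25 each. The territory of Irf2bpl was 106 kb and that of Pde4d 1402 kb.

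**Figure D3:**
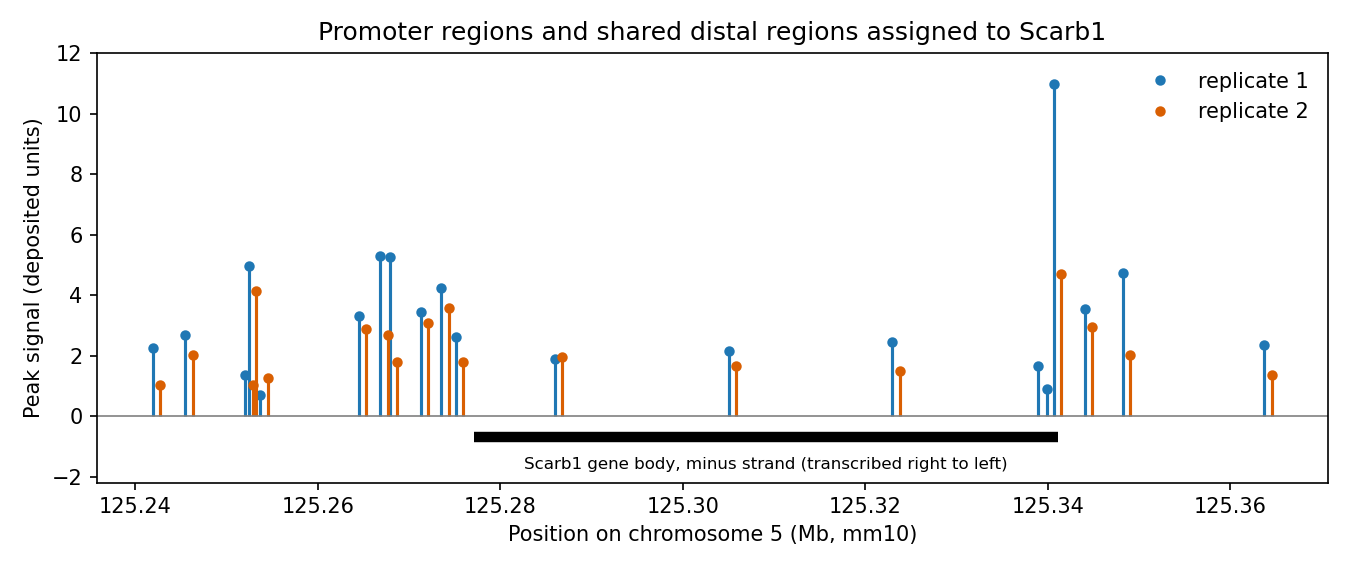
Promoter regions and shared distal regions assigned to Scarb1 by position (Mb on chromosome 5, mm10), with the signal of the peak in each replicate as a line and point and the gene body as a black bar. The promoter peak (10.97 and 4.70) stands at the right end of the gene, which is on the minus strand, and the distal region with the highest mean signal (4.95 and 4.13) lies beyond its left end.

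The motif of the steroidogenic factor SF-1 (NR5A1), which related nuclear receptors also bind, was enriched at distal peaks, along with those of CTCF, AP-1 and CREB/ATF factors. The ratio compares the share of 200 bp windows at peak centres that hold the motif with that in windows 1 kb to each side. It was 2.95 ± 0.703 (SD, n = 2) for NR5A1, from 2.47% of distal peaks in replicate 1 (ratio 2.45, 95% exact interval 2.31 to 2.60) and 3.37% in replicate 2 (3.44, 3.20 to 3.70). At promoter peaks the NR5A1 ratio was 0.772 ± 0.0329. The other 5 of the 6 highest distal ratios were those of REST, a repressor of neuronal genes (69.5 ± 3.54, from 4 and 2 windows with the motif in the flanks), CTCF (33.3 ± 7.57), NFI (14.0 ± 1.30), the CRE motif of CREB and ATF factors (4.08 ± 0.750) and the AP-1 motif of FOS and JUN factors (3.72 ± 1.08), which 10.5% and 16.3% of distal peaks held. The 3 lowest were POU (0.616 ± 0.00720), HNF1 (0.390 ± 0.309) and PHOX2 (0.338 ± 0.00723). Of the 26 motifs, 19 had a distal ratio whose 95% exact interval lay above 1 in both samples. At promoters NRF1 (12.7 ± 3.796), the ETS promoter motif (8.84 ± 2.18) and CRE (7.49 ± 1.41) had high ratios. With the motif written backwards as background, the NR5A1 ratio was 5.90, and CRE (0.737) and the ETS promoter motif (0.267) fell below 1 at distal peaks while POU (15.7) rose above it.

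**Figure D4:**
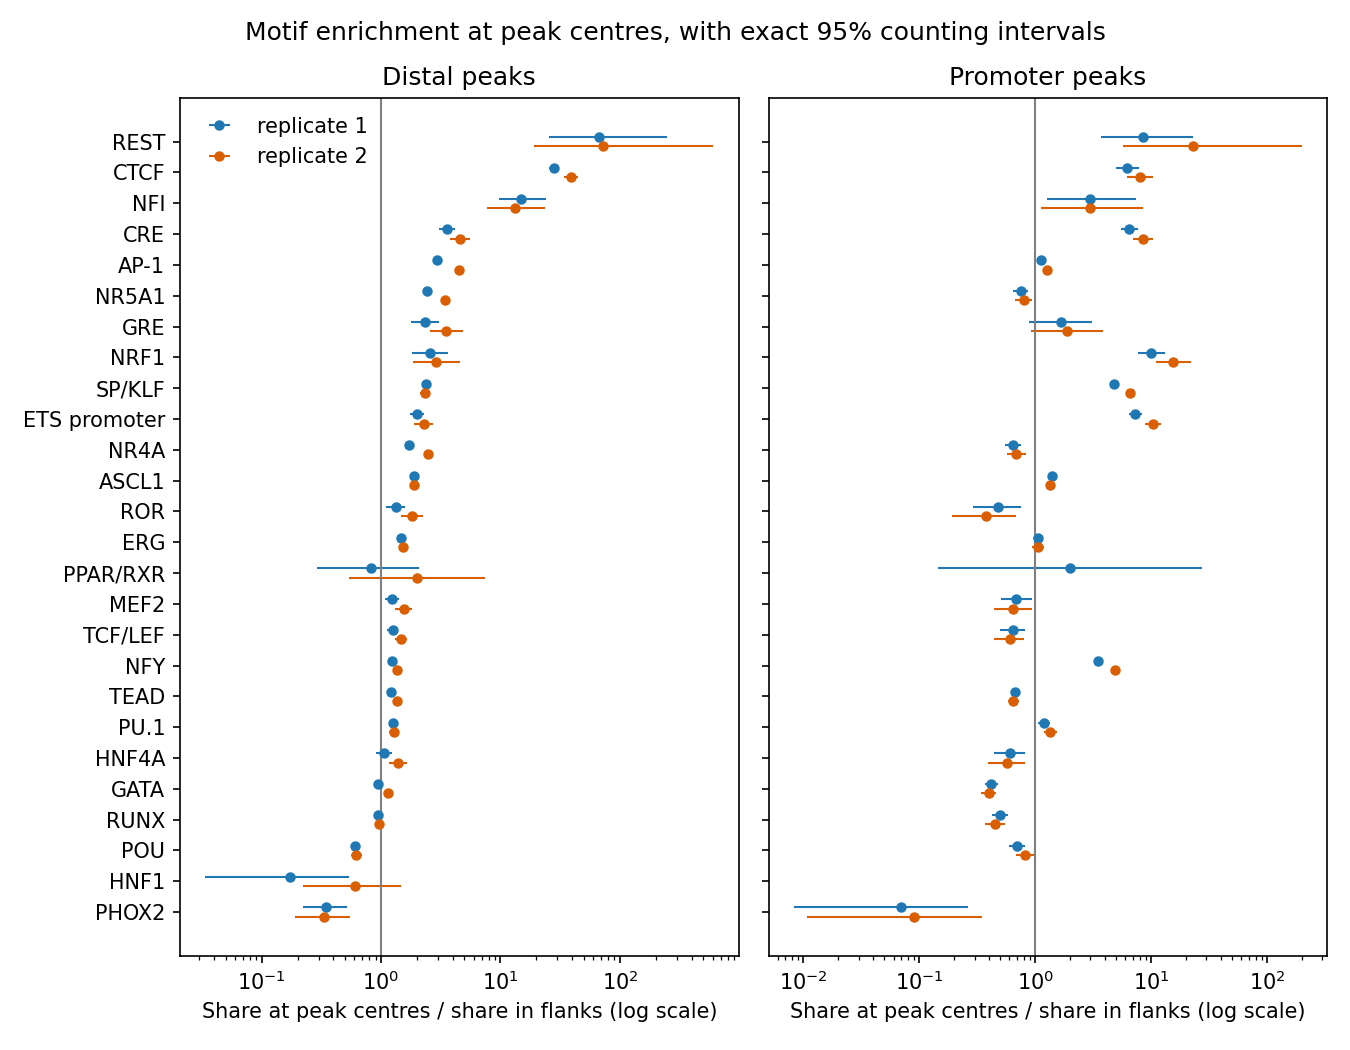
Ratio of the share of windows with each motif at peak centres to that in flanks (log scale) for distal and promoter peaks, one point per replicate with its exact 95% interval. REST and CTCF are highest at distal peaks (means 69.5 and 33.3), NR5A1 lies above 1 at distal peaks (2.95) and below 1 at promoters (0.772), and motifs with no finite interval above 0 have no point.

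Footprints, short stretches protected from cutting inside accessible chromatin, numbered 500920 in replicate 1 and 275005 in replicate 2. Of these, 67.7% and 71.2% touched a peak, and 88.1% and 89.3% of peaks held one. Control intervals were of equal width in the same peaks and touched no footprint of their own sample. NR5A1 motifs were found in footprints at 6.66 times (95% exact interval 5.71 to 7.80) the rate of control intervals in replicate 1, and at 8.19 times (6.75 to 10.01) in replicate 2. The ratios were 189 and 122 for CTCF, 39.6 and 38.1 for CRE, 9.84 and 8.54 for SP/KLF, 2.00 and 2.41 for AP-1 and 0.561 and 0.510 for GATA. REST motifs lay in 148 and 86 footprints and in 0 control intervals of either sample. Of the footprints inside peaks, 37.6% in replicate 1 overlapped a footprint of replicate 2, compared with 10.2% of control intervals. In replicate 2, 66.9% overlapped one of replicate 1, compared with 27.6%. Where the samples share footprints, the choice of control intervals lowers their overlap, so 10.2% and 27.6% are not rates of random placement.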

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

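No test in this part was run. Sequence with an FDR of the cut rate of at most 0.001 but outside the longer peak list came to 16.3 Mb in replicate 1 and 6.93 Mb in replicate 2. It is a signal in data that the comparisons of the report do not use.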

How the results depend on the processing

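The same number of top peaks and the CpG matching in one replicate at a time for promoter lists, and the matching on promoter signal for distal lists were chosen after seeing the data, and the other alternatives were planned. Where no cause is named, the cause was not tested. The alternative of a stricter footprint threshold was not run, because every footprint has the same deposited value. Replicate 2 had 83475 peaks compared with 128446, and whether depth sets this was not tested.

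The share of replicate 1 peaks found in replicate 2, and the reverse, became 48.5% and 74.6% with an overlap of at least 50% of both peaks, 59.8% and 91.8% with peaks above the median signal, 74.1% and 74.3% with the same number of top peaks, and 54.4% and 84.2% with the longer lists. The promoter share of peaks became 30.6% within 2 kb and 38.4% above the median signal, and ranged from 24.7 to 28.0% with one replicate.

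Of 22 promoter lists, 14 passed the threshold. The number was 5 with CpG-matched lists, 3 to 6 with these in one replicate, and 13 to 15 under the other alternatives (13 to 14 with one replicate). Steroidogenesis lay 23.7 percentage points above other genes, 13.5 with the 5′-most TSS, 21.5 above the median signal, 20.02 with the same number of top peaks and 21.5 to 27.9 with one replicate. The chromaffin list lay 17.4 points below other genes above the median signal (-17.4), -3.53 with CpG matching, and 10.02 to 22.9 with one replicate (-3.72 to 7.72 CpG-matched). Lists past the threshold in neither setting changed direction as follows. Capsule became 18.5 points with the longer list, 6.45 with CpG matching and -5.93 to 16.3 with one replicate (5.39 to 25.1 CpG-matched). Schwann became 0.754 with the 5′-most TSS, 2.79 with the longer list, 9.57 with CpG matching and -3.07 to 0.577 with one replicate (9.07 to 10.8 CpG-matched). Gonadal somatic became 7.28 with CpG matching (6.52 to 7.31 with one replicate). The cortical neuron list ranged from -23.1 in replicate 2 to 17.3 in replicate 1 (-34.6 to 4.55 CpG-matched), and its CpG-matched call was kept in replicate 2 only, as was that of kidney, and immune gained one there. The erythroid list, past the threshold in Fisher's exact test, became 0.904 with CpG matching (-5.44 to 0.0509 with one replicate) and lost its call, and liver, also past it, became -13.3 to 5.01 with CpG matching in one replicate and lost its call.

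Calls in Fisher's exact test were lost for steroidogenesis with the same number of top peaks, steroidogenesis and pancreas above the median signal, and steroidogenesis, erythroid and glucocorticoid response with the 5′-most TSS. They were also lost for erythroid within 2 kb, pancreas and glucocorticoid response with the longer list, and these 2, kidney and steroidogenesis in replicate 1 alone. Calls were gained for cortical zonation and adipocyte within 2 kb, in replicate 1 alone and with the longer list. They were also gained for adipocyte with the 5′-most TSS and the same number of top peaks, cortical neuron with the 5′-most TSS and above the median signal, endothelium with the longer list, and chromaffin in replicate 1 alone. Cortical zonation, endothelium and chromaffin were past the threshold in no CpG-matched comparison.

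The number of distal lists past the threshold was 3 under every alternative run, and the same 3 except where lists were not matched (2 of the same 3). Steroidogenesis was 2.02-fold there and 2.26 to 3.96 with one replicate, and chromaffin 0.801 to 0.860. Lists that never passed crossed 1. Within 50 kb, chromaffin was 1.16, Schwann 1.23 and liver 0.912. Not matched, chromaffin was 1.41, immune 0.666, Schwann 1.21, liver 0.919, muscle 0.979 and cortical neuron 1.196. Above the median signal, liver was 0.437, muscle 0.582 and cortical neuron 1.09. With one replicate, the values of replicate 1 alone being the highest except for immune and liver, Schwann was 0.925 to 1.31, kidney 0.884 to 1.02, cortical neuron 0.895 to 1.29, gonadal somatic 0.634 to 1.11, immune 0.946 to 1.01 and liver 0.863 to 1.02. Matched on promoter signal, cholesterol synthesis was 0.931, Schwann 1.16, kidney 1.25 and germ cell 1.01.

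The NR5A1 ratio was 5.90 with the reversed motif as background, 4.17 in 100 bp windows and 2.45 to 3.44 with one replicate. The number of motifs with an interval above 1 was 16 to 21. With reversed motifs CRE became 0.737, the ETS promoter motif 0.267 and POU 15.7, where reversal removes a CpG dinucleotide from CRE and ETS and adds one to POU. The NR5A1 footprint ratio was 6.66 to 8.19 with one replicate, and footprints overlapping one of the other sample 30.02 to 58.7%.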

Other observations

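The tests of peak strength, base composition and cortical share for the steroidogenic pattern were chosen after the values of all 22 lists had been seen, as was the pattern itself. A pair of tests of the chromaffin promoters, on signal and on CpG content, was set aside after its percentiles, given here, had been seen. The tests of the chromaffin distal regions, of distal crowding and of the GATA flanks were written before their results. The 22 lists were compared between replicates with no correction for their number, and the margin around the 2.5 percentile was set after the values were seen. These ratios rest on the authors' signal being comparable between samples, and the design has no group that separates the replicates, so no biological explanation tied to a group was tested.

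Peaks found in one sample only differed in sequence. Equal numbers of top peaks were taken from each sample and distal ones absent from the other's longer list were kept, 6502 in replicate 1 and 3427 in replicate 2. For replicate 2 these top peaks were all of its 83475, and for replicate 1 the strongest 83475 of 128446. The longer lists held 210257 peaks in replicate 1 and 136015 in replicate 2. The 2 sets may therefore differ in strength and in how strictly absence was judged. The AP-1 motif was in 4.55% of those in replicate 1 and 23.7% of those in replicate 2, NR5A1 in 1.37% and 4.61%, and GATA in 1.66% and 5.57%. CTCF went the other way, with 4.75% and 2.39%, as did SP/KLF, with 3.38% and 0.379%. Mean GC content was 54.9% and 45.8%. With replicate 1 weighted to the GC content of replicate 2, NR5A1 was 4.003 times and CTCF 0.247 times as frequent in replicate 2. AP-1 was 6.13 and GATA 3.93 times as frequent. For SP/KLF the difference narrowed, from 0.112 times without weighting to 0.375 times with it. The strongest distal region by mean signal, chosen after its value was seen, lay between protein-coding genes at chromosome 17, 39846781 to 39846920. Its signal was 68.4 and 31.1. A region at chromosome X, 143482981 to 143483140, between protein-coding genes and nearest to Pak3, had 7.62 and 51.3. Whether either lies in a gene of another kind, and whether reads could be placed uniquely there, was not tested.

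Steroidogenic regions were relatively stronger in replicate 2, and chromaffin regions tended the other way. The median log2 ratio of replicate 1 over replicate 2 was 0.56 at steroidogenic promoters, compared with 0.91 in lists matched on signal. The percentile was 0.31, and 1.58 with CpG content matched too. The 0.31 met the condition set against peak strength, but the pattern was picked with such percentiles in view, so it is no separate test. The distal regions of these genes lay below all 10000 sets matched on signal and GC content (percentile 0), so matching on base composition did not remove the difference. These 84 regions came from 16 genes, 17 of them at Scarb1 and 10 at Mc2r, while matched sets were drawn region by region. Regions near 1 gene may share a ratio, so the distal percentiles given here may be too extreme. A lower cortical share in replicate 1 that raises every other cell type alike is not settled, because the endothelial promoters had a percentile of 1.98 matched on signal but 4.73 with CpG content matched. Distal regions matched on signal did not agree among the other cell types of the gland, with high percentiles for immune (99.69) and Schwann cell genes (97.42) but 37 for capsule, 32.27 for endothelial and 62.52 for erythroid genes. Chromaffin promoters had percentiles of 97.55 and 97.15 and their distal regions 96.44 (93.38 with GC content matched), short of the percentile that the test of a larger medullary share required, so that share may differ or not. The pattern was not confined to the gland's own genes, since distal regions of immediate early (0.74), glucocorticoid response (1.08) and housekeeping genes (2.31) also had low percentiles and those of cortical neuron (99.99) and epidermis genes (99.61) high ones. Shared distal regions also differed by motif when matched on signal. Those with AP-1 had a median log2 ratio of -0.0214 compared with 0.379, and those with NR5A1 0.0763 compared with 0.307 (percentile 0 for both). Those with CTCF had 1.16 compared with 0.603, and those with REST 1.70 compared with 0.678 (percentile 100 for both). These motifs were picked after their values were seen. Whether the lists follow this difference between motifs was not tested.

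Distal regions crowded around immediate early and steroidogenic genes, and strong promoters attracting peaks is one technical explanation. With random lists matched on territory and promoter signal the fold was 2.31 for immediate early genes (permutation p = 0.000200, the smallest that 10000 lists can give) and 1.79 for steroidogenic genes (permutation p = 0.0052), down from 2.99 and 2.22, so the excess was smaller with promoter strength matched but still past 0.05. No biological explanation was tested.

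The GATA motif was less frequent in distal peaks than in flanks in replicate 1, with a ratio of 0.940 (95% exact interval 0.895 to 0.988), and more frequent in replicate 2, with 1.15 (1.08 to 1.22), although GATA factors act in the adrenal gland. Base composition of the flanks is a candidate explanation, since the motif written backwards was depleted in the same windows (0.612 and 0.667), and the ratio of the 2 ratios was 1.54 and 1.72. Footprints had GATA ratios of 0.561 and 0.510, which this does not address.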
